A study of Mus musculus with 3 samples.

How the data were processed

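RNA was measured by sequencing in 3 libraries of wild-type mouse primary neurons from the hippocampus, the brain region of memory formation. All 3 belonged to 1 group, neurons given fresh neuronal medium with the B27 supplement and penicillin-streptomycin. Per the labels, the cells were kept in Neurobasal with 10% B27 and 1% GlutaMAX at 5% CO2 and 37 °C, and total RNA was sequenced on the DNBSEQ platform of BGI. A treatment time of 24 h is given for these 3 libraries. The series design also names neurons given apoE particles for 24 h. Those libraries were not analysed here, so no comparison between treatments was made. Nothing in the labels says that the 3 libraries came from separate cultures or animals, so the spread between them may be technical. Whether the library kit or the counting kept the strand is not given in the sources used here.

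The authors deposited 1 log2 expression value per gene and library, without a header line. Per the submitters' processing notes, the tools were FastQC, HISAT2, featureCounts and DESeq2 on the GRCm38 genome; versions, settings and roles are not given in the sources used here. The 47593 gene rows were the same in the 3 libraries, and 21897 of them were exactly 0 in all 3. A value of 0 in that block stood for no reads, whereas a value just below 0 stood for about 3 reads over the 3 libraries. Names of 27 rows had been turned into dates by a spreadsheet, and these rows were left unnamed.

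The deposited log2 values had the form of a regularized log, in which the differences between libraries of a gene with few reads are pulled almost to 0. Genes with 1 read over the 3 libraries, 3097 in number, took only 3 patterns of values. The SD of the deposited values therefore understates the spread between libraries. The reads behind the values were recovered by inverting the equation of a ridge-penalised negative binomial fit, with 6 parameters fitted over all genes. Of 67797 values, 99.8% came within 0.1 of a whole number of reads, against 20% by chance. In abundance ranges not used for the fit at that stage, 98.7% to 100% of values were whole. Refitting the log2 values from the recovered reads gave the deposited values to within 0.001 for 100% of genes. Recovery was weakest for the 71 genes with a mean log2 value of 14 or more, where 80.8% of values came within 0.1 of a whole number, but the distance was at most 0.0025% of such a gene's reads. The recovery was chosen after seeing the data, and everything computed from recovered reads is an added alternative to the deposited values.

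Recovered reads summed to 18780563, 18683971 and 18885657 in replicates 1, 2 and 3. At this depth a gene with no reads in a library lay below about 0.16 CPM (counts per 1000000), the value of 3 reads. Intervals and floors of this kind cover counting error only, since reads without molecular identifiers are not independent molecules.

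Gene names were matched to GENCODE M21, an annotation of GRCm38, which gave coordinates, exon lengths and GC content; 45729 distinct names matched, 603 of them by an older symbol. Exon length is the union of all annotated exons of a gene, which can be longer than the transcript expressed. Detection meant at least 1 CPM in each library, with 2 raised to the deposited value and divided by its sum over genes. A list's share is the sum of such values over its members in percent of the sum over all genes. Levels printed as CPM with an SD come from recovered reads. Gene pair and gene list ratios were log2 differences within a library of levels per kilobase, with 0.5 added to each gene's level, averaged over the 3 libraries. They were tested with a two-sided exact sign-flip permutation test, whose smallest p with 3 libraries is 0.25, with Benjamini-Hochberg adjustment over the gene pairs and over the list pairs. List ratios used the mean of the members' log2 levels. Where levels were summed instead, the sum was not divided by the number of members, so it also reflects list size.

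The 36 gene lists (402 genes), the 14 gene pairs, the 9 list pairs, the tests and the rule for named genes were fixed before the data were examined. Lists covered neurons of several classes, other cell types of brain tissue, receptors and synapses, apoE receptors and lipid handling, senescence, stress responses, and sex-linked genes. Named genes were both members of each pair, the 3 highest members of each list, the members below 1 CPM in every library, the 10 highest genes, and the 10 genes with the smallest p for variation between libraries. Some genes under this rule are not reported here. Further genes in the text were chosen after their values were seen.

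Variation between libraries had been planned as negative binomial models of read counts. The deposited log2 values are not counts and cannot enter such models, so recovered reads of 15131 genes with a mean of 10 reads or more were tested with a Pearson chi-square statistic on 2 degrees of freedom. Expected reads used median-of-ratios size factors. The statistic was set first against Poisson counting error and then against a dispersion trend estimated from the median statistic in 30 abundance bins, with Benjamini-Hochberg adjustment and a threshold of 0.05. Shifts of a list in 1 library were medians over members of the deposited log2 value minus the mean of the other libraries, placed among 10000 random lists of the same size matched on expression in 20 bins. Tested on simulated data with 200 genes changed in 1 library, the trend test called 42.6%, 88.9% and 100% of genes changed by 0.25, 0.5 and 1 log2 units, and 0.054% of 14919 unchanged genes. The Poisson test called 3.05% of the unchanged genes, which had been simulated with extra variation. All simulated genes shared 1 dispersion, smaller than the median of the fitted trend in every range of abundance. Changed genes were drawn only from those with 100 expected reads or more. These shares therefore do not give the share called among genes of 10 to 100 reads, or at the variation of the real libraries.

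Alternatives planned beforehand were other detection minimums, pseudocounts and filters, ratios without length scaling, medians or sums over list members, totals without mitochondrial genes, other size factors and each library left out in turn. Alternatives added after seeing the data were the recovered reads and size factors fitted in 10 GC content by 5 length bins of nuclear genes. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.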

Results

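RNA sequencing of cultured wild-type mouse hippocampal neurons given fresh medium gave 3 libraries, replicates 1 to 3 of a single group, the fresh-medium arm of a design that also names apoE particles. Recovered reads numbered 18780563, 18683971 and 18885657, and a read was found for 22244 to 22321 genes per library. At 1 CPM (count per 1000000) or more in every library, 13986 genes were detected, 12762 of them protein coding and 211 long intergenic noncoding. The deposited values behind this count differ little between libraries, and the same rule on recovered reads gave 13648 genes. Mitochondrially encoded genes were highest, with mt-Co1, a subunit of cytochrome c oxidase, at a mean deposited log2 value of 18.81, followed by mt-Cytb, mt-Nd1, mt-Nd4, mt-Nd5, mt-Nd2 and the ribosomal mt-Rnr2. The highest nuclear genes were the translation elongation factor Eef1a1 (3600 ± 59.0 CPM), the tubulin Tuba1a (3519 ± 73.4) and Dpysl3 (2820 ± 21.8), a protein of axon growth. Throughout, levels in CPM are means ± SD of recovered reads over the libraries (n = 3), and values named log2 are the deposited ones.

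The first question was which cells the cultures held. All 18 pan-neuronal genes were detected, and together they took 1.00% of the summed expression. Mapt, which encodes the microtubule protein tau, was highest at 2032 ± 39.4 CPM, followed by the dendritic protein gene Map2 (1528 ± 50.8) and Stmn2 (1025 ± 11.9), a regulator of axonal microtubules. Mapt lies on chromosome 11 from 104231390 to 104332090 in GRCm38. Dcx, a marker of young neurons, reached 686 ± 21.7 and Rbfox3, which encodes the mature neuronal antigen NeuN, 147 ± 7.22 CPM, a Dcx over Rbfox3 ratio per kilobase of 1.10 ± 0.06 (log2, SD; 2.22 without length scaling). The same ratio had an SD of 0.12 in recovered reads, so that it exceeded the spread between libraries on both scales.

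Astrocyte genes were well expressed, with 11 of 12 members detected and a share of 0.231%. The glutamate transporter Slc1a3 led at 980 ± 9.44 CPM, with Atp1b2 at 309 ± 30.4 and Aldoc at 224 ± 9.34, and the astrocyte filament gene Gfap lay at 146 ± 1.73. Atp1b2 is also made by neurons, and Gjb6 stayed below 1 CPM. All 10 neural progenitor genes were detected (share 0.116%), led by Fabp7 at 622 ± 22.9, Vim at 260 ± 13.4 and Sox2 at 98.1 ± 5.09; these genes are expressed by immature astrocytes too. Of 6 oligodendrocyte precursor genes 5 were detected, led by Olig1 (159 ± 9.64), Olig2 (67.1 ± 0.14) and Pdgfra (28.4 ± 0.46), with Gpr17 below 1 CPM.

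Genes of mature oligodendrocytes, microglia and vessels were near or under the detection limit. Of 8 oligodendrocyte genes, 4 were detected, led by Cnp at 22.9 ± 0.67, Mbp at 21.5 ± 1.69 and Mog at 9.80 ± 0.71, while the myelin genes Mag, Mobp and Cldn11 had 2, 1 and 11 reads in all and Opalin had none. Of 14 microglial genes, 5 were detected, among them Cd68 at 3.11 ± 0.61 and the complement genes C1qa at 1.79 ± 0.54, C1qb and C1qc. Below 1 CPM lay Cx3cr1, Csf1r, Itgam, Aif1, Ptprc, Tyrobp, P2ry12 and Tmem119, with 6 to 50 reads each, and Trem2, with 1 read. Endothelial genes took 0.00063% of the expression, with Kdr at 4.03 ± 0.21 and Esam at 1.03 ± 0.27; Pecam1, Tek, Flt1, Cdh5 and Ly6c1 had 42, 16, 9, 4 and 1 reads, and Cldn5 had none. Mural and fibroblast genes were led by Dcn at 23.2 ± 0.92, Acta2 at 19.8 ± 1.02 and Pdgfrb at 9.21 ± 1.39, with Rgs5 and Lum below 1 CPM and Kcnj8 without reads. A gene without reads in a library could still be present there at up to 0.16 CPM, and the bound is lower for genes without reads in any library.

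Set against each other per kilobase within a library, pan-neuronal genes lay above astrocyte genes by 2.18 ± 0.005 log2 units as the mean of members. Their distance above progenitor genes was 2.47 ± 0.004. When levels were summed before the logarithm the distances were 2.35 and 1.60, so the order of astrocyte and progenitor genes depends on the measure. Such sums, over 18 pan-neuronal, 12 astrocyte and 10 progenitor genes, also reflect list size. As the mean of members, the distances were 4.68 for oligodendrocyte precursor, 7.0 for mural and fibroblast, 7.5 for microglial, 7.96 for oligodendrocyte and 9.85 for endothelial genes. The SD of these 7 distances in recovered reads was 0.02 to 0.33. Each had the same sign in 3 of 3 libraries, with an exact permutation p of 0.25 (adjusted 0.25), the smallest that 3 libraries allow.

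**Figure D1:**
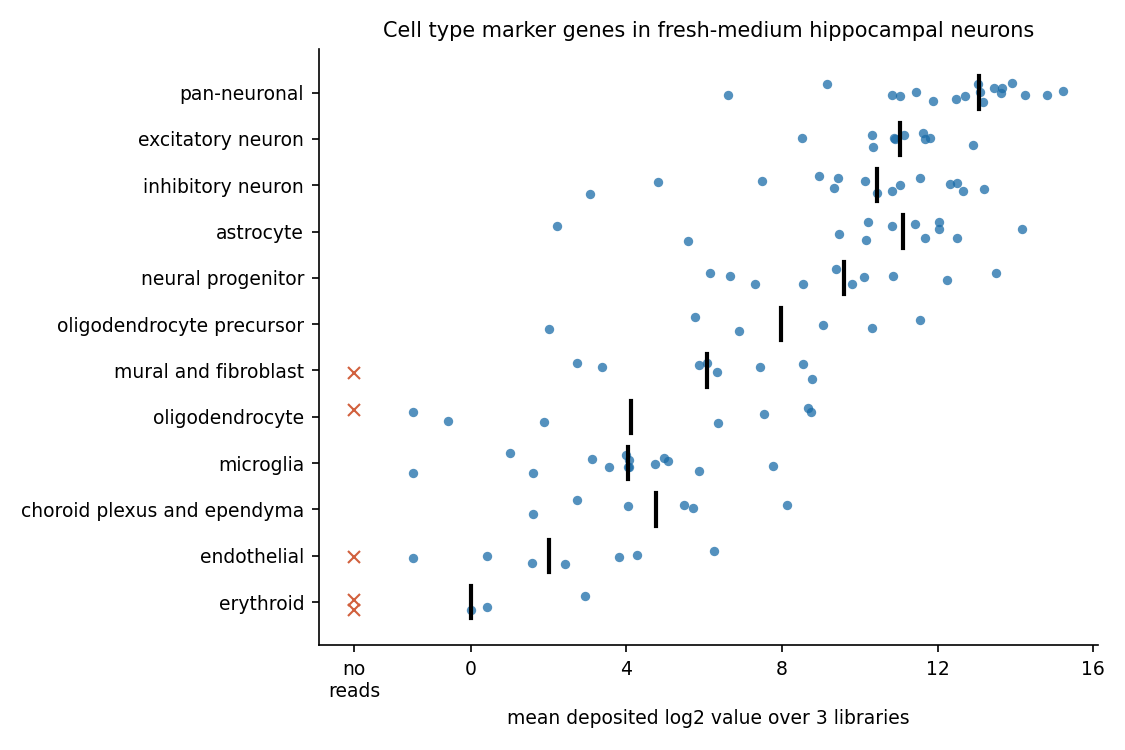
Mean deposited log2 value of each marker gene (points, 1 per gene, mean over 3 libraries) for 12 cell type lists; vertical bars are list medians and crosses are genes without reads in any library. Pan-neuronal genes reach 15.22 (Mapt) and astrocyte genes 14.17 (Slc1a3).

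Excitatory and inhibitory neuron genes were both expressed. All 10 excitatory genes were detected, led by the transcription factor gene Neurod6 (406 ± 10.2 CPM), the kinase gene Camk2a (191 ± 3.56) and Nrgn (175 ± 17.8). Of 15 inhibitory genes 14 were detected, among them the GABA-synthesising enzyme Gad1 (340 ± 3.5) and Reln (308 ± 7.32); Sst reached 271 ± 9.81, whereas Pvalb had 25 reads in all. Excitatory genes lay above inhibitory genes by 0.66 ± 0.01 log2 units as the mean of members and by 0.02 as the median. They lay below them, at −0.72, when levels were summed before the logarithm. The sums ran over 10 and 15 genes and were not divided by these numbers, which lowers the ratio. Slc17a7, the vesicular glutamate transporter VGLUT1, exceeded Slc17a6 (VGLUT2) by 0.85 ± 0.07 and Gad1 exceeded Gad2 by 0.72 ± 0.006; in recovered reads the SDs were 0.17 and 0.01. Slc12a5, the chloride exporter KCC2, exceeded the importer gene Slc12a2 by 2.39 ± 0.02. Among hippocampal field genes, 8 of 10 were detected, led by Zbtb20 (108 ± 4.76), Wfs1 (58.8 ± 2.49) and Nectin3 (52.9 ± 2.68), while C1ql2 and Dsp had 49 and 38 reads. Prox1, like these 2 a gene of the dentate gyrus, was detected at 21.5 ± 0.63.

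Synaptic genes were expressed throughout, with all 18 presynaptic and all 14 postsynaptic genes detected. Presynaptic genes took 0.565% of the expression and were led by Cplx2 (672 ± 21.4 CPM) and Syt1 (592 ± 14.1), both of vesicle release; Syp, Syt1 and Snap25 are also in the pan-neuronal list. Postsynaptic genes took 0.243%, led by Camk2b (438 ± 10.4) and the scaffold genes Dlg2 (356 ± 9.43) and Dlg4 (295 ± 18.7).

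Among receptor genes, subunits of AMPA receptors were highest. All 9 AMPA and kainate receptor genes were detected, led by Gria2 (622 ± 25.8), Gria1 (249 ± 12) and Grik3 (183 ± 2.82). Gria2 and Gria1 did not differ by more than the spread once scaled for exon length (−0.04 ± 0.04, with an SD of 0.07 in recovered reads), but without length scaling Gria2 lay higher by 1.32. Of 7 NMDA receptor genes 6 were detected, led by Grin2b (357 ± 13.1), Grin1 (101 ± 5.47) and Grin3a (40.2 ± 2.29), with Grin3b below 1 CPM. Grin2b, the subunit that predominates in young neurons, exceeded Grin2a by 3.25 ± 0.04 log2 units, a 9.53-fold ratio. Grm5 (258 ± 6.14) and Grm7 (43.9 ± 1.20) led the metabotropic receptors, of which 7 of 8 were detected and Grm6 had no reads. All 12 GABA-A receptor genes were detected, among them Gabra5 (209 ± 13.6).

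**Figure D2:**
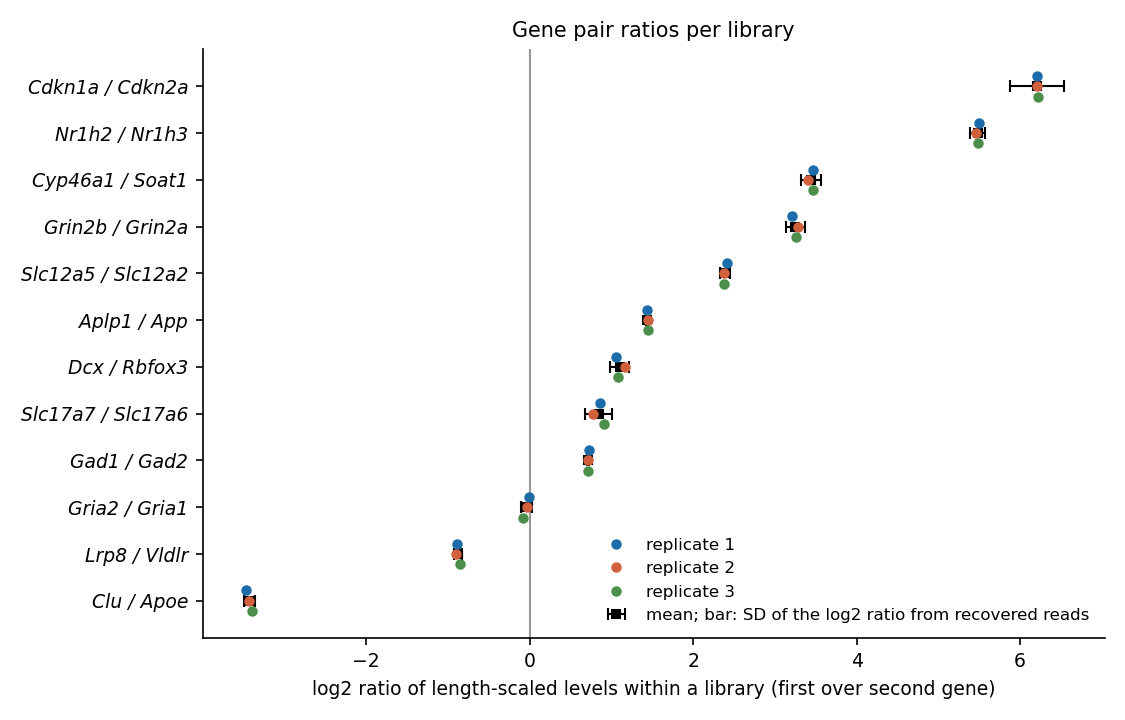
Log2 ratio of length-scaled levels for 12 of the 14 gene pairs; coloured points are the 3 libraries from deposited values, black squares their means, and bars the SD of the ratio in recovered reads. Only the Gria2 over Gria1 ratio, −0.04, lies within its SD of 0.07 from 0.

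Receptors and carriers of apoE, the lipoprotein that the wider series concerns, were themselves expressed without added particles. All 10 apoE receptor genes were detected, led by Lrp1 (404 ± 19.4 CPM; chromosome 10, 127538161 to 127621148), the sorting receptor Sort1 (237 ± 2.52) and Vldlr (210 ± 4.29). Lrp8, the other reelin receptor, lay below Vldlr at −0.88 ± 0.02 log2 units. Apoe itself (chromosome 7, 19696109 to 19699188) was among the highest genes at 1224 ± 35.9, above the cholesterol exporter Abca1 (223 ± 4.21) and Clu (183 ± 7.63), and the Clu over Apoe ratio was −3.43 ± 0.03. Of the 13 apolipoprotein and lipid transport genes 10 were detected; Apoa1, Apoc1 and Apob had 14, 13 and 1 reads.

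Cholesterol genes were mostly detected. Of 21 genes of cholesterol synthesis 20 were found, led by Hmgcs1 (197 ± 2.33), the regulator Srebf2 (168 ± 4.16) and Cyp51 (166 ± 2.63). Fdps had 42 reads in all, a value that is uncertain because near-identical copies could take or remove its reads. Of 8 genes of cholesterol turnover and sensing 5 were detected, led by Cyp46a1 (79.99 ± 4.03), the enzyme of neuronal cholesterol clearance, Npc2 (74.8 ± 0.85) and Npc1 (60.4 ± 1.90). Cyp46a1 exceeded Soat1 by 3.44 ± 0.03 (1.87 without length scaling), and Nr1h2 (LXR beta) exceeded Nr1h3 (LXR alpha) by 5.48 ± 0.02 with 27 reads for Nr1h3; Ch25h and Cyp27a1 had 6 and 2 reads.

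All 13 genes of amyloid precursor processing were detected, at 0.316% of the expression. App reached 1265 ± 22.9 CPM, Aplp1 796 ± 11.4 and Aplp2 538 ± 10.0. Aplp1 exceeded App by 1.44 ± 0.006 log2 units per kilobase but lay below it at −0.67 without length scaling. The annotated exons of App sum to 12996 bases and those of Aplp1 to 3017.

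Senescence genes were expressed unequally. Of 13 regulators 12 were detected, led by Hmgb1 (293 ± 10.7 CPM) and the cell cycle inhibitor genes Cdkn1b (211 ± 6.97) and Cdkn1a (85.4 ± 0.72), which encode p27 and p21. Cdkn2a, which encodes p16 and p19ARF, had 5, 8 and 7 reads, and Cdkn1a exceeded it by 6.21 ± 0.006 log2 units per kilobase, with an SD of 0.33 in recovered reads. Secreted factors of senescent cells lay below the regulators at −3.59 ± 0.004 as the mean of members (SD 0.05 in recovered reads). When levels were summed before the logarithm the ratio was −0.39. Those sums ran over 26 factors and 13 regulators and were not divided by these numbers, which raises the ratio. Of 26 such factors 13 were detected, led by Igfbp5 (274 ± 15.4), Igfbp3 (169 ± 1.82) and Vegfa (142 ± 1.70). The cytokine genes Tnf, Cxcl2, Il1a, Il1b and Il6 had 34, 17, 8, 5 and 3 reads, Ccl4, Ccl5, Mmp12, Timp1, Spp1 and Tgfb1 had 14 to 49, and Mmp3 and Csf2 had none.

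Of the 14 gene pairs, 10 had the first gene higher and 4 the second gene higher in each library. With the exception of Gria2 and Gria1, every ratio was several times its SD, which was 0.01 to 0.33 in recovered reads. The exact permutation p was 0.25 for each pair (adjusted 0.25), which is the smallest that 3 libraries allow, so that no ratio could pass a threshold of 0.05.

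The replicates were compared to see which genes differed between libraries given the same medium. Mitochondrially encoded genes were prominent among them. The list held 6.51%, 7.58% and 6.99% of recovered reads in replicates 1, 2 and 3, and each of its 13 genes was lowest in replicate 1. mt-Co3 had 9503, 14730 and 11740 reads, a 1.57-fold range between libraries after scaling by size factors (adjusted p = 6.45e-18, chi-square test against the dispersion trend). The other genes with the 10 smallest p values were mt-Tn, mt-Nd3, mt-Nd4l, mt-Co2, Gm10925, Gm28438, Gm13340, Gm28661 and Gm17383, with ranges of 1.39-fold (Gm28661) to 2.23-fold (mt-Tn). Values of the predicted genes among these are uncertain where they resemble mitochondrial sequence, and so are those of overlapping or antisense mitochondrial genes.

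**Figure D3:**
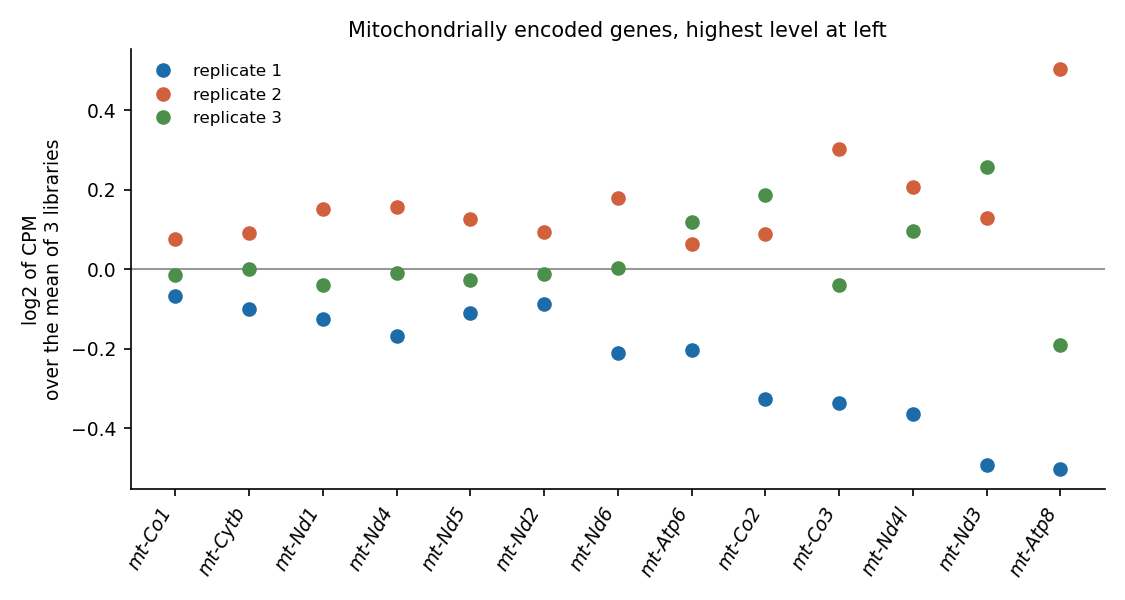
CPM of the 13 mitochondrially encoded genes in each library, as log2 of the ratio to the mean of the 3 libraries, with the highest gene (mt-Co1) at left; points are single libraries. Replicate 1 is the lowest library for 13 of 13 genes.

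Of 15131 genes tested, 1304 differed between libraries by more than counting error and 50 by more than the dispersion trend. Among the 50 were the synaptic gene Syn1, the receptor gene Gabrb2, Xist and Atp1b2, named after their values were seen. Without replicate 2 the first count was 329, and after fitting size factors in GC content and length bins it was 728. The second count was 9 without replicate 1 and 73 with GC content and length bins. The trend corresponded to a coefficient of variation between libraries of 7.5% for genes with 10 to 100 reads and 3.1% for genes with 1000 to 10000 reads.

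Small shifts of gene lists in 1 library were also seen. Mitochondrially encoded genes lay at −0.17 in replicate 1 and at 0.10 in replicate 2 (deposited log2, median of members minus the other libraries), outside the central 95% of random lists. Among the other lists outside that range the largest shift was −0.04, for excitatory neuron genes in replicate 2. Presynaptic, postsynaptic, NMDA receptor and inhibitory neuron genes lay at 0.03, 0.03, 0.03 and 0.02 in replicate 3, the last 3 of these lists at −0.04, −0.03 and −0.02 in replicate 2, presynaptic genes at −0.02 in replicate 1, and GABA-A receptor genes at 0.03 in replicate 2. In all, 16 of 96 list-by-library values lay outside, where 4.8 are expected by chance for independent lists, and 15 after removal of the GC content and length trend, which brought the NMDA receptor and postsynaptic shifts in replicate 2 to −0.01 and −0.02. Shifts were larger in recovered reads, which lack the shrinkage, and their order changed: −0.31 and 0.24 for mitochondrially encoded genes in replicates 1 and 2, −0.13 and 0.13 for NMDA receptor genes in replicates 2 and 3, and −0.12 for excitatory neuron genes in replicate 2. Microglial genes lay at −0.28 in replicate 1, at percentile 2.5 of random lists and so not counted as outside.

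Deposited values agreed closely between libraries, with a lowest Pearson r of 0.99994 across 15131 genes, which are not independent replicates. In recovered reads the lowest r was 0.9968. The recovered reads of each pair of libraries differed by more than sampling noise, with a chi-square per gene of 2.27 for replicates 1 and 3 to 3.86 for replicates 1 and 2, so the 3 were counted as separate libraries. For genes with log2 values of 3 to 5 the median SD was 0.0026 in deposited values and 0.31 in recovered reads.

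**Figure D4:**
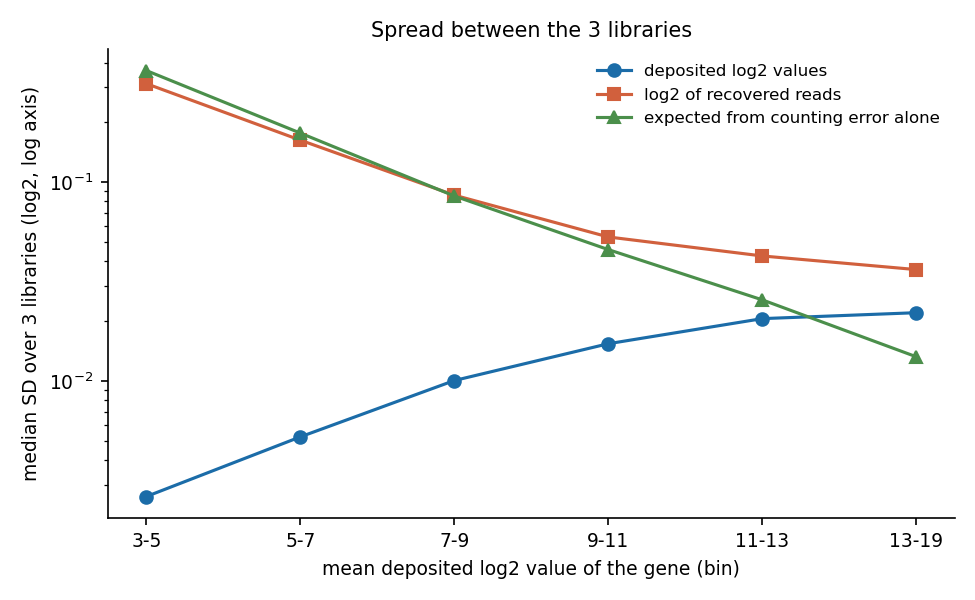
Median SD over the 3 libraries (log2 units, log axis) by mean deposited log2 value, for deposited values, recovered reads and counting error alone. In the lowest bin the medians are 0.0026, 0.31 and 0.36, and in the highest bin 0.022, 0.036 and 0.013. Counting error is drawn as the SD of the counting distribution itself, whereas the median of sample SDs from 3 libraries tends to lie below the true SD. The lowest bin therefore does not show that recovered reads vary less than counting error.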

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

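The recovered reads and the GC content and length bins were chosen after the data were seen. Over all results, 377 alternative values were computed, of which 330 were the same, 44 moved and 3 reversed. Same meant within 1 SD for a share or correlation, the same direction for a ratio and within 1.5 times for a count. Leaving out 1 of 3 libraries could not move a share beyond 1 SD. It also could not reverse a ratio with the same sign in 3 of 3 libraries, which held for every ratio. Those outcomes were fixed in advance, so the 330 overstates how much was tested. The reversals were Gria2 over Gria1 (1.32) and Aplp1 over App (−0.67) without length scaling, and excitatory over inhibitory genes on the summed level (−0.72). The first 2 follow from exon length. For the third, sums were not divided by the number of members, 10 and 15, which lowers the ratio. The cause of the rest of that difference was not tested. The other 144 alternative gene pair and list ratios kept their direction, but some changed in size: secreted senescence factors over regulators went from −3.59 to −0.39 on the summed level, excitatory over inhibitory genes from 0.66 to 0.02 with medians, and without length scaling Cyp46a1 over Soat1 went from 3.44 to 1.87 and Dcx over Rbfox3 from 1.10 to 2.22. The lowest correlation between libraries moved from 0.999938 to 0.999978 without a filter, 0.999903 with a pseudocount of 5 and 0.996779 in recovered reads, which lack the shrinkage. Genes beyond counting error numbered 329 to 1105 with 1 library left out (329 without replicate 2, 758 without replicate 3) and 728 with GC content and length bins, which gave 73 genes beyond the trend. Genes beyond the trend numbered 9 to 29 with 1 library left out (9 without replicate 1, 20 without replicate 2), a test with fewer libraries. Other size factors and filters kept both counts within 1.5 times. Shares of 35 lists moved only when mitochondrial genes left the total. Detection stood between 11289 and 15207 genes at minimums of 5 and 0.5 CPM. TMM scaling was run for the count of detected list genes, not for each list's share. No paired analysis was possible because only 1 group was analysed. Depth limits genes under about 10 reads per library, whose ratios rest on counting error.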

Other observations

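Most stress genes not described so far were detected, at levels that differed widely. All 10 genes of the integrated stress and unfolded protein response were detected (share 0.204%), led by Asns (592 ± 15.6 CPM, SD, n = 3), the transcription factor gene Atf4 (427 ± 16.4) and Sesn2 (279 ± 4.78). Heat shock genes took 0.286%, led by Hspa8 (1693 ± 17.5), Hsp90aa1 (995 ± 24.6) and Hsph1 (110 ± 3.79), while the inducible genes Hspa1b and Hspa1a lay at 5.77 ± 0.64 and 3.07 ± 0.20 and Hspb1 had 19 reads. All 13 antioxidant genes were detected, led by Gpx4 (248 ± 7.03), Prdx1 (181 ± 5.13) and Sod1 (138 ± 6.80) with Nqo1 lowest at 1.72 ± 0.40, and so were all 10 apoptosis genes, among them Mcl1 (127 ± 2.92) and Bcl2l1 (103 ± 7.30). All 17 immediate early genes were detected, led by Fosl2 (114 ± 3.15), Jun (82.0 ± 5.46) and Nr4a3 (62.4 ± 1.06).

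Interferon-response genes were low: 2 of 11 were detected, among them Ifitm3 at 3.57 ± 0.43, and the 9 not detected (Bst2, Isg15, Ifit3, Oasl2, Irf7, Usp18, Ifit1, Rsad2 and Mx1) had 1 to 22 reads. Of 17 proliferation genes 16 were detected, led by Pcna (81.6 ± 2.27), Mcm7 (69.5 ± 2.37) and Mcm6 (36.4 ± 1.00); Mki67 lay at 6.16 ± 0.54 and Aurkb had 54 reads. Choroid plexus and ependyma genes were led by Foxj1 (15.0 ± 1.39), Ttr (2.79 ± 0.43) and Otx2 (2.38 ± 0.05), with Kl, Clic6 and Folr1 below 1 CPM. Of 5 erythroid genes none was detected: Alas2, Hba-a2 and Hba-a1 had 23, 4 and 3 reads, and Hbb-bs and Hbb-bt had none.

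Among the tests that follow, those of library size and both on sex-linked genes were chosen after the result was seen, as was the use of recovered reads. The readings of the respiratory chain and cell mixture tests were also changed after their first results were seen. For the chain, the same order of libraries and a wide range had both been asked for beforehand. Its first reading used the range of the nuclear genes alone, which would have read as support. The mixture test had counted a range inside the central 95% as argument enough against a mixture. No biological explanation was tested by the design, which has 1 group here.

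The 13 mitochondrially encoded genes had a median range between libraries of 1.26-fold. Library totals differed by a factor of 1.01, too little to account for it. After size factors were fitted in GC content and length bins of nuclear genes, the genes kept 1.07 times their former range. That argues against the trend seen in nuclear genes as the whole cause. Such bins cannot remove a trend among genes that share a bin, and a length trend among the 13 genes was not tested. In replicate 1 their log2 CPM over the mean of the 3 libraries ran from −0.07 (mt-Co1) to −0.50 (mt-Atp8). More respiratory chain RNA in some libraries would put the nuclear and mitochondrial genes of the chain in the same order of libraries. That order was not seen. The 78 nuclear genes of the chain had a wide range, at percentile 99.99 of random lists, so the bound on the range set beforehand against this explanation was not met. In replicate 1, where the mitochondrial genes were lowest, the nuclear genes lay 0.0494 log2 units above the other libraries (0.0272 with GC content and length bins). In replicate 3 the nuclear genes were lowest, at −0.0619 (−0.0548 with the bins), and the mitochondrial genes lay at 0.0018 (0.0606 with the bins). These values argue against a joint shift of both sets in replicates 1 and 3, but do not bear on mitochondrial transcripts alone. A difference in the handling of mitochondrial RNA between libraries stays open and was not tested.

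The 1304 genes beyond counting error may share a technical part. Across genes, GC content correlated with a library's deviation at a Spearman rho of 0.14, −0.33 and 0.23 in replicates 1 to 3, and the count fell to 728 with GC content and length bins, which is in line with GC or length bias for part of it. The count beyond the dispersion trend was 50 before and 73 with these bins. The trend was estimated anew with the bins, so the counts rest on different trends and do not bear on the bias. A varying mixture of cells could not be decided from astrocyte markers, whose median range lay at percentile 84.5 of random lists. That lies inside the central 95%, the bound set beforehand against a mixture, but above most random lists, so that a small difference is not excluded. Among the neuron lists the range in recovered reads lay at percentile 98.48 for excitatory, 64.23 for inhibitory and 61.15 for pan-neuronal genes.

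The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in the 3 libraries, while Xist, the RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254), reached 1142 ± 109 CPM and percentile 99.8 of genes. All 4 had a row, which argues against their having been left out of the counting. A candidate explanation is that the cultured cells came from female animals; the labels given here state no sex. On 5 of 1568 Y chromosome rows, 269 reads were counted, mostly on pseudogenes (Gm21857 held 190), where reads from similar sequence elsewhere are possible. Tsix, antisense to Xist, had 4 reads.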
